A study of Mus musculus with 6 samples.

How the data were processed

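The study measured polyA RNA of single cells from whole mouse aortas in 6 libraries, 2 for each of 3 groups: db/+ mice given vehicle, db/db mice given saline, and db/db mice given dapagliflozin (DAPA), a drug that blocks the sodium-glucose cotransporter SGLT2. Per the labels' protocols, each library pooled the aortas of 4 mice, DAPA was given by oral gavage at 1 mg/kg/day for 4 weeks and then at 3 mg/kg/day for 2 weeks, aortas were digested with Liberase, elastase and DNase for 45 minutes at 37 °C, and libraries were made with the 10x Chromium 3′ kit, version 3.1. The labels put both db/+ libraries in batch 2 and the 4 db/db libraries, treated or not, in batch 1. Batch and genotype therefore cannot be told apart, and only DAPA against untreated db/db lies within 1 batch.

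The deposited matrices hold raw UMI counts per gene and cell barcode, made with Cell Ranger 6.1.1 per the file headers, for 32285 genes. Per the submitters' processing notes the build was mm10, and Seurat 3.5 was also named; the matrices hold whole numbers with no sign of scaling. The lowest total of any deposited barcode was 500 or 501 UMIs, so barcodes had been filtered before deposit. How barcodes were filtered is otherwise not given in the sources used here. Gene positions came from GENCODE vM21 on GRCm38, the assembly that mm10 names, and 32158 of the 32285 gene IDs (99.6%) matched it.

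Cells were kept with at least 500 genes and at most 10% mitochondrial UMIs. Scrublet's automatic threshold marked under 0.5% of barcodes in every library, so the fallback fixed in advance was used. The cutoff was the score reached at an expected 0.8% per 1000 barcodes, and all cells at or above it were removed. Ties at the cutoff made each library lose more than expected, for example 13.15% against 12.15% in db/+ replicate 2. Counts were log-normalized, 2000 variable genes and 30 principal components were taken, and Leiden clusters were made on 15 neighbours at resolution 1 without batch integration (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0 on Python 3.11.15). Clusters were named from 21 marker sets, each name needing at least 3 of its markers. The names carry "-like" because they rest on markers alone. A class was tested where each of the 6 libraries held at least 20 of its cells, which left smooth muscle-like, fibroblast-like, endothelial-like and macrophage-like cells.

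Cells are not replicates, so raw UMI counts were summed per library and class. Per class, edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment; R 4.3.3) fitted all 6 libraries together, with 3 residual degrees of freedom, and gave 3 contrasts: db/db against db/+, DAPA against db/db, and DAPA against db/+. A gene counts as changed at an adjusted p under 0.05. With 2 libraries against 2, no exact permutation test can go under the threshold, so every call rests on the spread that edgeR pools over genes. Log2 fold changes are edgeR's, their standard errors came from the same fits, and levels are CPM, the class's counts scaled to 1e+06 after TMM, given as mean ± SD of 2 libraries. Shares of cell classes were tested with edgeR on numbers of cells, with exact Clopper-Pearson intervals at 95% for single libraries, which cover counting error only. Levels over all cells, and levels compared between classes, use unscaled library totals. A limit for a count of 0 was taken as 3 counts.

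A set of 30 gene lists was fixed before the data were examined, as were the cell filters, the classes' markers, the tests and the rule for named genes. The lists covered the contractile apparatus, collagens, elastic fibre and other matrix, matrix proteases and inhibitors, modulated smooth muscle, adipose, inflammatory and chemokine, interferon response, antigen presentation, glucocorticoid-induced, circadian clock, dissociation and immediate early, fatty acid oxidation and handling, cholesterol synthesis and uptake, cholesterol efflux and liver X receptor, glycolysis, glucose-responsive and insulin signalling, oxidative phosphorylation, mitochondrially encoded, oxidative stress defence, unfolded protein response, ribosomal proteins, transforming growth factor beta and BMP, proliferation, senescence, vasoconstriction and vasodilation, endothelial function, resident macrophage, lipid-associated macrophage, and SGLT and leptin receptor genes. Of the listed symbols, 6 matched no single gene (Ccl19, Mx1, Cyr61, Aldoa, Ddit3 and Sepp1). The list of SGLT and leptin receptor genes had fewer than 5 tested members in every class and was not tested. The others were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a class and contrast. Camera was run again with an estimated correlation, and fry beside it.

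The rule for named genes took, in each contrast and class, genes past the threshold with a mean log2 CPM of at least 5, both libraries of one group above both of the other, and a class level at least 0.1 times that in the class where the gene was highest. Gene models without a name were left out. In smooth muscle-like cells the 8 largest rises and 8 largest falls were named, in the other classes 3 of each. Some genes that these rules took are not reported here. For each list described, up to 4 members with the smallest adjusted p were taken as well, and Lepr, Slc5a2 and Slc5a1 in every library.

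Whether the change differed between classes was tested with the class by group interaction in edgeR, with library as a block, for smooth muscle-like against fibroblast-like and against endothelial-like cells. Genes changed in db/db were sorted by whether they were also called, in the same direction, in DAPA against db/+. Because both comparisons share the db/+ libraries, 20 simulations drew all 6 libraries anew with no change between groups. They gave the agreement that a shared control group produces where no gene is changed.

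The steps were tested on simulated data with known changes, laid on db/db against db/+ over all genes tested (15130 in smooth muscle-like, 11347 in fibroblast-like, 9470 in endothelial-like and 8331 in macrophage-like cells). In smooth muscle-like cells, 65.7% of genes changed 1.5-fold, 85.1% changed 2-fold and 97.0% changed 4-fold were called, and 21 of 186 calls (11.3%) were false. The shares called at 2-fold were 58.2% in fibroblast-like, 52.2% in endothelial-like and 37.3% in macrophage-like cells. Of the 2-fold differences between classes, 44.8% (smooth muscle-like and fibroblast-like) and 35.8% (smooth muscle-like and endothelial-like) were called, with 12 of 107 and 5 of 85 calls false. Camera called the shifted list in 20 of 20 draws and 0 of 560 unmoved lists. Genes were drawn independently of each other there, so these draws do not test whether the preset correlation holds for the measured data.

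Alternatives were fixed at the same time: RLE size factors in edgeR, no filter on low counts, DESeq2 1.42.0, a fit of the 2 groups compared only, the replicate number as a block, each library left out in turn, doublets kept, stricter cells (at least 1000 genes, at most 5% mitochondrial UMIs), looser cells (at least 200 genes, at most 20%), clusters at resolution 2, counts thinned to the smallest library, and leaving out genes whose class level was under 0.1 times that in their highest class, which free RNA from other cells could give. A fit without mitochondrial genes, and a fit of smooth muscle-like cells from 1 cluster shared by all libraries, were added after the data were seen. Where a library is left out, its group's lone library is assumed to vary like the others. No library was excluded from the results as reported.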

Results

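Transcripts of single cells from whole mouse aorta were counted in db/+ mice, which carry 1 mutated copy of the leptin receptor gene, in obese and diabetic db/db mice, which carry the mutation on both copies, and in db/db mice treated for 6 weeks with the SGLT2 inhibitor dapagliflozin (DAPA). Each group had 2 libraries of 4 pooled aortas, so n is 2 libraries throughout and mice within a pool cannot be told apart. The series title states the question: which changes of aortic smooth muscle persist when glucose is controlled. The libraries of db/+ replicates 1 and 2, db/db replicates 1 and 2, and DAPA replicates 1 and 2 held 89645525, 118536425, 128224629, 65160777, 114652629 and 46142812 UMIs on 9329, 15189, 10522, 6686, 10863 and 5281 barcodes. Of these, 6991, 7265, 8561, 5474, 8617 and 3926 cells were kept, with median depths of 10303.5 to 12459 UMIs per cell. The mitochondrial limit removed 15% and 41.7% of the barcodes of the db/+ libraries, 8.39% and 9.21% of those of db/db, and 9.30% and 18.4% of those of DAPA.

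Smooth muscle-like cells made up most of every library: 84.7% ± 0.686 (SD) in db/+, 82.8% ± 3.38 in db/db and 82.6% ± 3.69 in DAPA. Fibroblast-like cells held 7.89% ± 1.22, 9.33% ± 1.87 and 10.3% ± 2.11, endothelial-like cells 2.59% ± 0.447, 3.63% ± 0.626 and 3.66% ± 0.670, and macrophage-like cells 2.75% ± 0.0351, 2.39% ± 0.572 and 2.04% ± 0.441. B, T, Schwann, erythroid and neutrophil-like cells each stayed under 1% of a library. No share of the 9 classes changed in edgeR's test. The smallest adjusted p was 0.798 for db/db against db/+, 0.982 for DAPA against db/db and 0.520 for DAPA against db/+. One class passed for db/db against db/+ without db/+ replicate 1, and 1 for DAPA against db/+ without db/+ replicate 2.

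Smooth muscle-like cells were also unevenly spread over clusters. Clusters 0 and 5 held 59.3% of the smooth muscle-like cells of db/+, 5.84% of those of db/db and 3.49% of those of DAPA, while clusters 1 and 2 held 3.40%, 50.8% and 49.5%. The median mitochondrial share of a smooth muscle-like cell was 5.42% and 6.67% in the db/+ libraries, 4.07% and 3.42% in the db/db libraries and 4.31% and 4.60% in the DAPA libraries. Across genes, which are not independent replicates, Pearson's r between smooth muscle-like profiles was 0.993 to 0.994 within groups, 0.991 to 0.996 between db/db and DAPA libraries, and 0.985 to 0.991 between db/+ libraries and the others. These ranges nearly meet, and genotype and batch split the libraries in the same way.

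The gene mutated in this model and the drug's targets come first. Transcripts of Lepr, the leptin receptor gene (chromosome 4, 101717404 to 101815352, GRCm38), stood at 7.92 and 8.28 CPM over all kept cells of the db/+ libraries, 2.38 and 2.68 CPM in db/db, and 2.35 and 1.73 CPM in DAPA. In smooth muscle-like cells the log2 fold change was −1.73 (SE 0.15, edgeR adjusted p = 0.000285) in db/db against db/+ and −1.98 (SE 0.16, adjusted p = 0.000154) in DAPA against db/+. Counts from 3′ ends of transcripts do not test the mutation itself, so they do not check the genotype labels. Slc5a2, which encodes SGLT2, had 5 to 18 UMIs per library (0.123 to 0.172 CPM). Slc5a1, which encodes SGLT1, had 0 to 4 UMIs. In the library with 0, DAPA replicate 1, the 3 counts that a 0 allows come to 0.0308 CPM. Differences of either transporter were not detectable at this depth.

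In smooth muscle-like cells, the genes that differed between db/db and db/+ aortas included a clock output gene, a metallothionein gene, 2 matrix genes and a gene of the sarcomere's Z-disc. Dbp, a clock-controlled transcription factor (chromosome 7, 45705088 to 45710203), rose from 23.3 ± 15.3 to 163 ± 52.9 CPM, a log2 fold change of 2.81 (SE 0.40, edgeR adjusted p = 0.00370). Tcap, which encodes the Z-disc protein telethonin (chromosome 11, 98383811 to 98384953), rose from 165 ± 21.8 to 586 ± 214 CPM (log2 1.83, SE 0.22, adjusted p = 0.00162). Among matrix genes, the small proteoglycan gene Aspn rose by 1.79 (SE 0.16; 32.4 ± 2.84 to 112 ± 31.2 CPM) and the matricellular gene Sparcl1 by 1.49 (SE 0.11; 182 ± 5.15 to 510 ± 1.83 CPM), with edgeR adjusted p values of 0.000356 and 0.000114. The potassium channel gene Kcnj15 rose by 1.58 (SE 0.09, adjusted p = 2.86e-05) and the metallothionein gene Mt2 (chromosome 8, 94172664 to 94173568) by 1.58 (SE 0.15, adjusted p = 0.000471). The largest named falls were Itih4 (log2 −1.19), the mitochondrial genes mt-Nd4l (−1.08), mt-Nd5 (−1.07), mt-Atp8 (−1.02) and mt-Nd4 (−0.97), the aggrecanase gene Adamts5 (−0.92), Map3k7cl (−0.91) and the deubiquitinase gene Otud1 (−0.89), with edgeR adjusted p values of 0.000281 to 0.0344. mt-Nd4l overlaps mt-Nd4 (mitochondrial genome, 9877 to 10173 and 10167 to 11544), and such pairs, with their nuclear copies, are uncertain as single genes. Leaving out 1 library moved or ended few of these calls: Dbp stood at 3.71 without db/+ replicate 2. mt-Atp8 lost its call without db/+ replicate 1 (−1.03), db/+ replicate 2 (−1.01) or db/db replicate 2 (−0.63), and Otud1 without db/db replicate 2 (−0.73).

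**Figure D1:**
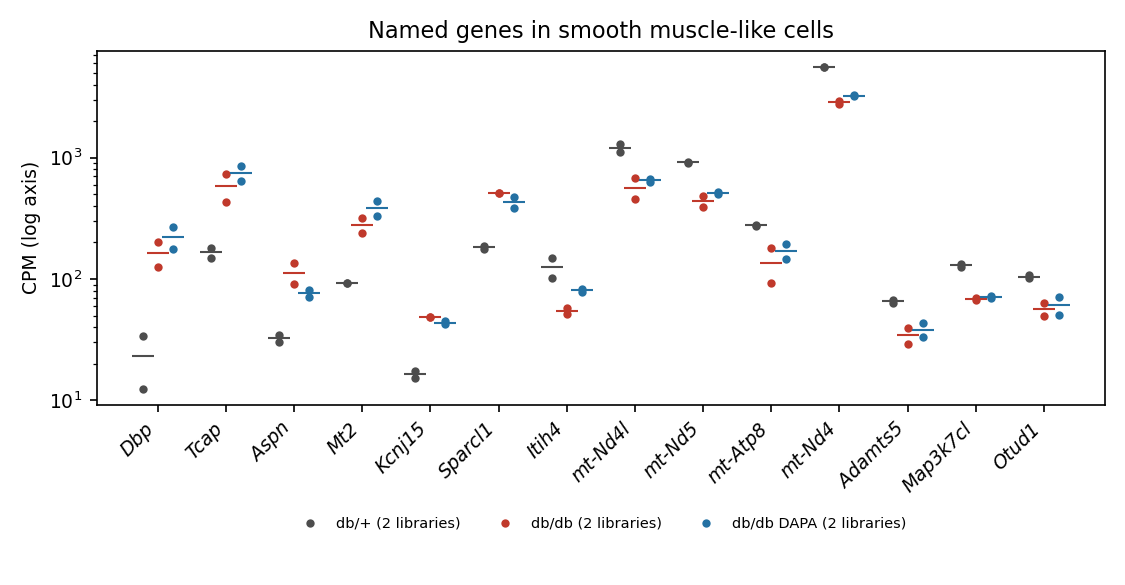
Levels of genes named by rule for db/db against db/+ in smooth muscle-like cells, in CPM on a log axis; each point is 1 library and each bar the mean of the 2 libraries of a group. Dbp stands at 23.3 CPM in db/+ and 163 CPM in db/db, and the DAPA libraries (223 CPM) lie beside the db/db libraries rather than the db/+ libraries.

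Of 15130 genes tested in smooth muscle-like cells, edgeR called 1049 in db/db against db/+, 558 higher and 491 lower. The number was 449 without db/+ replicate 1, 491 without db/+ replicate 2 and 448 without db/db replicate 2. These libraries also differ in batch and in the clusters they fill, so genotype and batch cannot be told apart.

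The lists fixed in advance were tested next, and none passed in any class with an estimated correlation. Fry passed 1 of 29 lists in smooth muscle-like cells of db/db against db/+ (modulated smooth muscle, fry adjusted p = 0.00871) and 10 of 29 in DAPA against db/+. It passed 2 of 28 in macrophage-like cells of db/db against db/+ (clock and oxidative stress defence), 1 of 29 in endothelial-like cells of DAPA against db/+ (glucocorticoid-induced), and 0 in the other 8 comparisons of a class. All 13 mitochondrially encoded genes fell when adjusted over the list alone, and 11 over all genes, with a median log2 fold of −0.74 (camera adjusted p = 1.81e-09, adjusted p = 0.51 with an estimated correlation); mt-Nd6 stood at −0.74. The nuclear oxidative phosphorylation list moved the same way by a median of −0.16 (camera adjusted p = 3.07e-05, adjusted p = 0.51 with an estimated correlation), though none of its 56 members was called, and in stricter cells, with at most 5% mitochondrial UMIs, its call was lost (−0.07). Glucocorticoid-induced genes rose, 12 of 19 over all genes and 16 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 5.16e-09, adjusted p = 0.51 with an estimated correlation). They included the metallothionein Mt1 (1.33; 667 ± 23.4 to 1672 ± 191 CPM), the kinase gene Sgk1 (0.68) and Pdk4, a brake on glucose oxidation (0.84). Of 17 clock genes 11 rose and 2 fell (12 and 3 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 0.000353, adjusted p = 0.552 with an estimated correlation). Beside Dbp, the clock repressor Bhlhe41 (1.19) and Tef (1.21) rose.

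Genes of modulated smooth muscle, markers of cells that leave the contractile state, rose with a median of 0.28 (camera adjusted p = 0.00013, adjusted p = 0.50 with an estimated correlation), 10 of 26 higher and 2 lower by either adjustment. The proteoglycan gene Acan rose by 1.40 (18.0 to 47.7 CPM), S100a4 by 1.03 (402 to 822 CPM), Comp by 1.37 and Spp1 by 5.13 (0.594 to 20.8 CPM), although Spp1 and Comp are far higher in another class and free RNA was not excluded for them. In stricter cells the median of this list was −0.21 (camera adjusted p = 0.515, range over its alternatives 1.85e-11 to 0.515), so its direction depends on the cell filter. That filter left 2155 of 5957 smooth muscle-like cells in db/+ replicate 1 and 597 of 6120 in db/+ replicate 2. Contractile genes showed a median of −0.12 with 1 of 30 called, Tpm1 (−0.56), by either adjustment (camera adjusted p = 0.0354, adjusted p = 0.693 with an estimated correlation). Acta2, the smooth muscle actin gene, was at −0.35 (SE 0.10, edgeR adjusted p = 0.064). The contractile call was lost without db/+ replicate 1 (−0.11), db/+ replicate 2 (−0.11) or db/db replicate 2 (−0.07), and Tpm1 lost its call without db/+ replicate 1 (−0.41), db/db replicate 1 (−0.57) or db/db replicate 2 (−0.56).

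A further 5 lists moved up in smooth muscle-like cells with camera's preset correlation, each losing the call without db/+ replicate 1 and without 1 db/db library. The immediate early list (6 of 33 higher, 7 adjusted over the list alone; median 0.22, camera adjusted p = 0.00675, adjusted p = 0.693 with an estimated correlation) had medians of 0.14 without db/+ replicate 1 and 0.05 without db/db replicate 1, and −0.07 in the 1 cluster shared by all libraries. Glucose-responsive and insulin signalling (5 of 25 higher, 7 adjusted over the list alone; 0.13, adjusted p = 0.0317, adjusted p = 0.51 with an estimated correlation) had 0.13 and 0.16 without the same libraries, and 0.18 without a call in the shared cluster. Inflammatory genes (4 of 30 higher, 9 adjusted over the list alone; 0.25, adjusted p = 0.0330, adjusted p = 0.667 with an estimated correlation) had 0.05 and 0.33, lost the call without genes that free RNA could give (0.19) and stood at −0.22 in stricter cells. Members of the lists above included Socs3, a brake on cytokine signalling (0.82), Igf2r of the glucose-responsive list (0.77) and Cebpd, a transcription factor of acute inflammation (1.17). Socs3 belongs to the immediate early, glucose-responsive and inflammatory lists alike. Lipid-associated macrophage genes (3 of 16 higher, 4 adjusted over the list alone; 0.18, adjusted p = 0.0323, adjusted p = 0.693 with an estimated correlation) lost the call without db/+ replicate 1 (0.12) or db/db replicate 2 (0.04). They also lost it without genes that free RNA could give (0.06), in stricter cells (0.08) and with no filter on low counts (0.08). Oxidative stress defence lost the call without the same 2 libraries (3 of 31 higher, 5 adjusted over the list alone; 0.08, adjusted p = 0.0455, adjusted p = 0.667 with an estimated correlation), with 0.05 and 0.06. It also lost it with the replicate number as block (0.11), with 2 groups only (0.08), in the shared cluster (0.07), in thinned counts (0.08) and without genes that free RNA could give (0.08). The oxidative stress list shares Mt1 and Mt2 with the glucocorticoid-induced list. Stricter cells also ended the calls of the immediate early (0.15), glucose-responsive (0.06), oxidative stress (0.09) and contractile (−0.01) lists.

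The other lists did not pass in smooth muscle-like cells of db/db against db/+. The camera adjusted p was 0.0526 for adipose, 0.0912 for glycolysis, 0.0992 for elastic fibre and other matrix, 0.112 for endothelial function, 0.221 for the unfolded protein response, and 0.265 each for proliferation, transforming growth factor beta and BMP, and fatty acid oxidation and handling. It was 0.290 for antigen presentation, 0.33 for senescence, 0.352 for collagens, 0.592 for cholesterol synthesis and uptake, 0.859 for the interferon response, 0.978 for cholesterol efflux, and 0.959 each for resident macrophage genes, matrix proteases, ribosomal proteins, and vasoconstriction and vasodilation.

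Within batch 1, DAPA left no single smooth muscle-like gene past the threshold, and 2 lists kept a call that rests on the preset correlation. Fry passed none there (smallest fry adjusted p 0.135). Genes of cholesterol synthesis and uptake rose as a list, with a median log2 fold of 0.28 (camera adjusted p = 5.3e-09, adjusted p = 0.716 with an estimated correlation) and 8 of 19 higher adjusted over the list alone. Idi1, an enzyme of the pathway, stood at 20.8 CPM in db/db and 29.9 CPM in DAPA (log2 0.52, edgeR adjusted p = 0.358). Collagens rose as a list by a median of 0.19 (camera adjusted p = 8.58e-05, adjusted p = 0.716 with an estimated correlation), with no member called by either adjustment and Col3a1 at 0.29. No left-out library ended these 2 calls.

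The count of genes in that comparison was 0 in edgeR (909 at an unadjusted p under 0.05, where 756.5 are expected by chance; smallest adjusted p 0.107) and 31 in DESeq2. It was 2 without db/db replicate 1 and 3 without DAPA replicate 1. Another 7 lists passed with the preset correlation and lost the call without at least 1 library. The mitochondrially encoded genes were higher by a median of 0.24 (camera adjusted p = 0.000221, adjusted p = 0.716 with an estimated correlation), which fell to 0.11 without db/db replicate 2 and 0.18 without DAPA replicate 2. Interferon response genes were higher by 0.17 with 2 of 27 members adjusted over the list alone (camera adjusted p = 0.00242, adjusted p = 0.716 with an estimated correlation), a call lost without db/db replicate 1 (0.19). The other 5, oxidative phosphorylation, senescence, clock, elastic fibre and oxidative stress defence genes, had medians of −0.12 to 0.21 and camera adjusted p values of 0.0292 to 0.0455 (adjusted p = 0.716 to 0.730 with an estimated correlation), and each lost the call without at least 3 of the 6 libraries in turn.

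Set against db/+, treated db/db aortas had higher levels of 3 clock genes, 2 metallothionein genes and Tcap in smooth muscle-like cells. Dbp rose by 3.25 (SE 0.41), Tcap by 2.17 (SE 0.23), Mt2 by 2.04 (SE 0.16), Mt1 by 1.74 (SE 0.13; 667 ± 23.4 to 2226 ± 382 CPM), and the clock genes Bhlhe41 and Tef by 1.67 and 1.63, with edgeR adjusted p values of 0.000137 to 0.00151. The named falls were Cacybp (−1.03), the LIM domain gene Lmcd1 (−1.02), the intermediate filament gene Nes (−0.99), the stress cytokine gene Gdf15 (−0.90), Tent5a, Rassf3 and the ligand gene Wnt16 (−0.89 each), and mt-Nd4l (−0.88), with adjusted p values of 0.000241 to 0.0173. Dbp stood at 4.15 without db/+ replicate 2. Tent5a lost its call without db/+ replicate 2 (−0.74) or DAPA replicate 1 (−0.69), and mt-Nd4l without DAPA replicate 1 (−0.85). In the 1 cluster shared by all libraries Gdf15 stood at −0.25 and was not called.

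Among 16 lists past the threshold in DAPA against db/+, 8 kept the call without any 1 library. Glucocorticoid-induced genes rose by a median of 0.69 (12 of 19, 17 adjusted over the list alone; camera adjusted p = 3.66e-09, adjusted p = 0.479 with an estimated correlation), with Fkbp5, a feedback gene of the glucocorticoid receptor, at 3.22 (3.80 to 36.0 CPM; 2.60 without DAPA replicate 2) and Tsc22d3 at 1.17. Clock genes rose by 1.17 (12 higher and 3 lower of 17 by either adjustment; camera adjusted p = 9.66e-05, adjusted p = 0.479 with an estimated correlation), with Hlf at 1.53. Mitochondrially encoded genes fell by −0.51 (5 of 13, 10 adjusted over the list alone; camera adjusted p = 4.46e-06, adjusted p = 0.479 with an estimated correlation). Genes of modulated smooth muscle (0.44; 10 higher and 3 lower of 26, 14 and 3 adjusted over the list alone), elastic fibre and other matrix (0.22; 10 and 3 of 39, 13 and 5), oxidative stress defence (0.19; 6 of 31, 9) and adipose function (0.51; 2 of 11, 5) rose, with camera adjusted p values of 0.000812, 0.00280, 0.00334 and 0.00369 (each adjusted p = 0.479 with an estimated correlation). Acan stood at 1.27, S100a4 at 1.17, Fn1, the fibronectin gene, at 0.92 and Cidea at 0.76. Contractile genes fell by −0.15 (0 higher and 3 lower of 30, 1 and 5 adjusted over the list alone; camera adjusted p = 0.00523, adjusted p = 0.596 with an estimated correlation). In stricter cells the modulated list stood at −0.09, the matrix list at 0.12 and the contractile list at −0.06, and all 3 calls were lost. Cholesterol synthesis rose by 0.19 (5 of 19, 7 adjusted over the list alone; camera adjusted p = 0.00192, adjusted p = 0.479 with an estimated correlation) and lost the call without DAPA replicate 2 (0.15). The 7 further lists that lost the call without a single library were inflammatory, immediate early, glucose-responsive, oxidative phosphorylation, unfolded protein response, endothelial function and lipid-associated genes, and they are not described further.

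In all, edgeR called 1157 smooth muscle-like genes in DAPA against db/+, 659 higher and 498 lower. The number was 566 without db/+ replicate 1, 611 without db/+ replicate 2, 596 without DAPA replicate 1 and 353 without DAPA replicate 2.

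Of the 1049 smooth muscle-like genes changed in db/db, 691 (65.9%) were also changed in the same direction in treated db/db aortas, 396 higher and 295 lower, and none in the opposite direction. Their sizes were close: genes higher in db/db had a median log2 fold of 0.66 without and 0.64 with DAPA, and genes lower in db/db −0.68 and −0.60. Of the 1049, 1043 had the same sign in both comparisons. No gene was called as moving back in DAPA against db/db by edgeR, and 7 were by DESeq2. At an unadjusted edgeR p under 0.05, 138 of the 1049 moved back and 66 further away. The 1049 were chosen from the same db/db libraries that DAPA is set against, which favours moving back without any drug effect. This split therefore does not show a reversal. Because both comparisons use the same db/+ libraries, unchanged groups were simulated. They gave 1.5 calls in db/db against db/+ and 0.25 shared calls on average (at most 1). With so few calls, the simulated count cannot tell how many of the 1049 shared controls alone would keep. Independent lists would share 24.3 higher and 16.2 lower genes. Pearson's r across genes between both sets of log2 folds was 0.81 against 0.49 simulated (0.479 to 0.520). The covariance was 0.150 against 0.0272 simulated. The db/+ libraries are too few to split, so part of the excess may come from the shared controls, and the shared batch enters both comparisons alike. The number kept was 314 without db/+ replicate 1, 338 without db/+ replicate 2, 393 without db/db replicate 2, 414 without DAPA replicate 1 and 303 without DAPA replicate 2, while the number moved back was 2 without db/db replicate 1 and 1 without DAPA replicate 1.

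**Figure D2:**
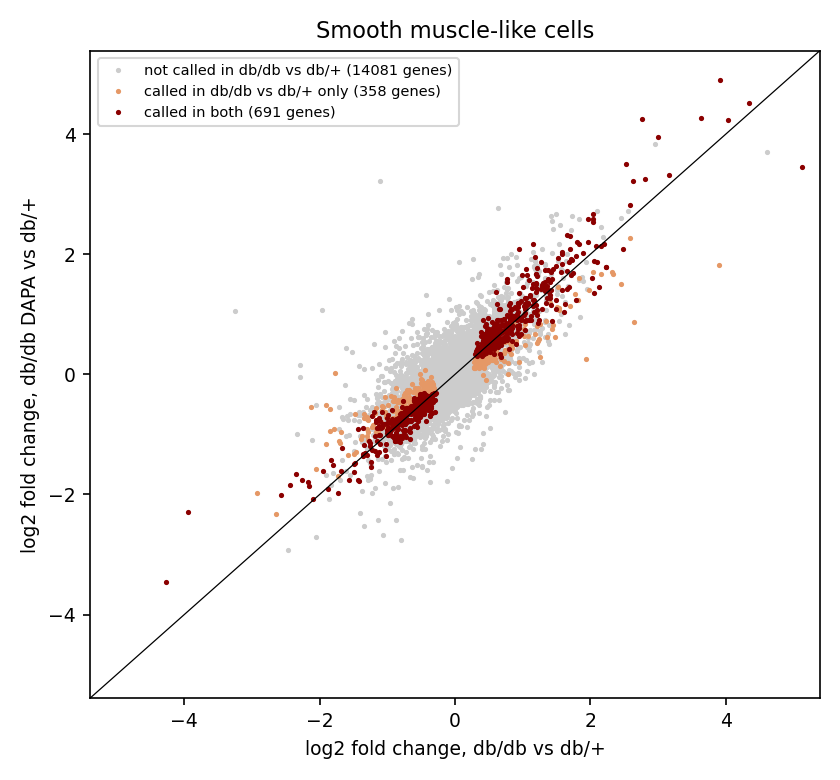
Log2 fold change of each gene in smooth muscle-like cells for db/db against db/+ (horizontal) and treated db/db against db/+ (vertical); each point is 1 gene, with the line of equal change. The 691 genes called in both comparisons lie along the line, and 358 were called in db/db against db/+ alone.

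In fibroblast-like cells, db/db aortas had more transcripts of a cartilage matrix gene than db/+ aortas. Comp, a cartilage oligomeric matrix protein (chromosome 8, 70373558 to 70382066), rose from 82.6 ± 21.2 to 453 ± 170 CPM (log2 2.45, SE 0.26, edgeR adjusted p = 0.0106). The transcription factor Zbtb16 rose by 1.98 (SE 0.32, adjusted p = 0.0277). The hyaluronan synthase gene Has2 fell by −1.43, Itih5 by −1.41 and the lipoprotein lipase gene Lpl by −1.18 (edgeR adjusted p = 0.0146, 0.0200 and 0.0148). Among these 5, Comp alone kept its call whichever library was left out. Zbtb16 lost its call without db/+ replicate 1 (1.80), db/+ replicate 2 (2.22) or db/db replicate 2 (1.36), and Has2 without db/db replicate 1 (−1.26). Itih5 lost it without db/+ replicate 2 (−1.05), db/db replicate 1 (−1.53) or db/db replicate 2 (−1.31), and Lpl without db/+ replicate 2 (−1.18) or db/db replicate 2 (−0.96).

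Of 11 lists past the threshold in fibroblast-like cells, 7 kept the call without any 1 library. Mitochondrially encoded genes fell by a median of −0.66 (4 of 13, 12 adjusted over the list alone; camera adjusted p = 2.6e-10, adjusted p = 0.396 with an estimated correlation), as did the median mitochondrial share of these cells (2.54% and 3.04% in db/+, 1.93% and 1.57% in db/db), so RNA quality was not set apart from it, and collagens by −0.21 (1 of 21, 2 adjusted over the list alone, camera adjusted p = 0.00543, adjusted p = 0.477 with an estimated correlation). Glucocorticoid-induced genes rose by 0.64 (5 of 20, 14 adjusted over the list alone; camera adjusted p = 6.11e-09, adjusted p = 0.312 with an estimated correlation) and inflammatory genes by 0.57 (4 of 31, 13 adjusted over the list alone, camera adjusted p = 1.32e-08, adjusted p = 0.396 with an estimated correlation). Immediate early genes, which tissue digestion can raise, rose by 0.24 (2 of 33, 8 adjusted over the list alone; camera adjusted p = 1.74e-06, adjusted p = 0.448 with an estimated correlation). Oxidative stress defence rose by 0.18 (2 of 30, 5 adjusted over the list alone) and clock genes by 0.51 (1 higher of 17, 6 and 1 lower adjusted over the list alone), with camera adjusted p values of 0.00132 and 0.00170 (each adjusted p = 0.396 with an estimated correlation). In all, edgeR called 108 of 11347 genes, 79 higher and 29 lower, against 19 without db/+ replicate 2, 20 without db/db replicate 1, 12 without db/db replicate 2 and 65 without DAPA replicate 1.

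Under DAPA, the collagen list of fibroblast-like cells was called with the preset correlation alone. It rose by a median log2 fold of 0.52, with 13 of 21 higher adjusted over the list alone and none over all genes (camera adjusted p = 2.36e-14, adjusted p = 0.602 with an estimated correlation). Col3a1 stood at 2272 CPM in db/db and 4111 CPM in DAPA (log2 0.86, edgeR adjusted p = 0.136) and Col1a1 at 2803 and 4376 CPM (0.64, adjusted p = 0.947). Elastic fibre and other matrix genes rose by 0.21 (camera adjusted p = 3.37e-06, adjusted p = 0.602 with an estimated correlation) and mitochondrially encoded genes by 0.35 (camera adjusted p = 2.54e-07, adjusted p = 0.602 with an estimated correlation; median mitochondrial share 1.93% and 1.57% in db/db, 2.17% and 2.43% in DAPA, so RNA quality was not set apart), in both cases with no member called by either adjustment. These 3 of 7 lists kept the call without any 1 library. The 1 gene called was Cthrc1, a collagen triple helix repeat protein (chromosome 15, 39076932 to 39087121), named because it was the only call: it rose from 16.1 and 22.2 CPM to 61.2 and 54.7 CPM (log2 1.62, SE 0.18, edgeR adjusted p = 0.0370). There were 467 genes at an unadjusted p under 0.05, where 567 are expected by chance, and DESeq2 called 3. Cthrc1 lost its call without db/db replicate 1 (1.40), db/db replicate 2 (1.86), DAPA replicate 1 (1.53) or DAPA replicate 2 (1.69), in stricter cells (1.64), at resolution 2 (1.43) and in thinned counts (1.52), and the count was 0, 0, 3 and 0 without these libraries.

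Against db/+, treated fibroblast-like cells kept the rise of Comp (log2 2.84, SE 0.26, edgeR adjusted p = 0.00260) and, beside it, had a rise of the matricellular gene Postn (1.99, SE 0.28, adjusted p = 0.0184). Fndc1 fell by −1.32, Itih5 by −1.27 and Lpl by −1.27 (edgeR adjusted p = 0.0378, 0.0249 and 0.0126). Cluster 17, where Fndc1 was among the 10 top genes, held 16.1% of fibroblast-like cells in db/+, 10.8% in db/db and 9.66% in DAPA, so a smaller share of such cells was not set apart from a fall within cells. Inflammatory genes (median 0.34), glucocorticoid-induced genes (0.61), clock genes (0.53) and oxidative stress defence (0.15) rose as lists and kept the call without any 1 library, with camera adjusted p values of 2.02e-07, 2.33e-07, 0.000656 and 0.00817 (adjusted p = 0.412 to 0.423 with an estimated correlation). Over all genes 5 of 31, 2 of 20, 1 of 17 and 1 of 30 of their members rose, and 8, 12, 7 and 2 adjusted over the list alone. EdgeR called 93 genes, 67 higher and 26 lower, and 56 of the 108 genes changed in db/db (51.9%) were called again in the same direction. Both comparisons share the db/+ libraries, and Pearson's r across genes between their log2 folds was 0.75, against 0.55 in simulated unchanged groups. Postn lost its call without DAPA replicate 2 (1.72), and Fndc1, Itih5 and Lpl lost theirs without db/+ replicate 2 (−1.14, −0.91 and −1.26), DAPA replicate 1 (−1.09, −1.05 and −1.2) or DAPA replicate 2 (−1.54, −1.46 and −1.30). The 93 were 12 without db/+ replicate 2, 24 without DAPA replicate 1 and 12 without DAPA replicate 2. The 56 were 8 without db/+ replicate 2, 16 without db/db replicate 1 and 10 without db/db replicate 2 or either DAPA library.

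**Figure D3:**
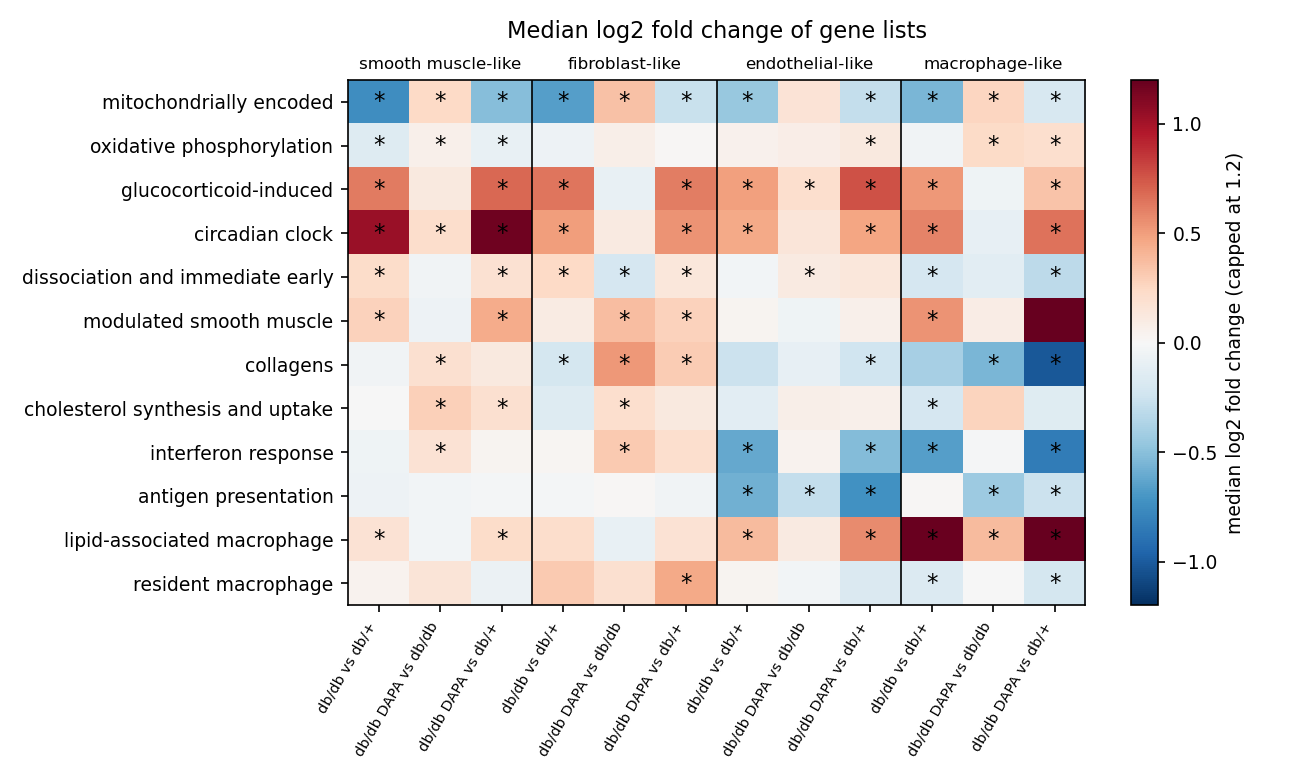
Median log2 fold change of gene lists (vertical) in each cell class and comparison (horizontal), on a colour scale capped at 1.2; an asterisk marks a camera adjusted p under 0.05 with the preset correlation. None passes with an estimated correlation; mitochondrially encoded genes are lower in db/db than in db/+ in all 4 classes, with medians of −0.74 in smooth muscle-like and −0.46 in endothelial-like cells.

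In endothelial-like cells, the interferon and antigen-presentation lists were lower in db/db than in db/+ aortas with the preset correlation alone. The interferon list fell by a median log2 fold of −0.62, with 1 of 27 members called over all genes and 13 adjusted over the list alone (camera adjusted p = 3.49e-12, adjusted p = 0.278 with an estimated correlation). Antigen presentation fell by −0.58, with 0 of 18 and 9 (adjusted p = 2.91e-08, adjusted p = 0.424 with an estimated correlation). Igtp, an interferon-induced GTPase, stood at 103 CPM in db/+ and 39.0 CPM in db/db (log2 −1.34, edgeR adjusted p = 0.0554). Glucocorticoid-induced genes rose by 0.49 with 0 of 20 and 6 (camera adjusted p = 7.04e-08, adjusted p = 0.233 with an estimated correlation), and mitochondrially encoded genes fell by −0.46 with 0 of 13 and 8 (adjusted p = 5.96e-07, adjusted p = 0.51 with an estimated correlation). The median mitochondrial share of these cells fell with them, from 3.43% and 4.19% to 2.55% and 2.83%. These 4 of 8 lists kept the call without any 1 library.

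Only 5 of 9470 endothelial-like genes were called in db/db against db/+, and all 5 are named, Cyp26b1 after its values were seen. Hpgd, which inactivates prostaglandins, rose from 38.5 ± 26.7 to 229 ± 79.0 CPM (log2 2.56, SE 0.35), and Cyp26b1, which degrades retinoic acid, from 3.93 and 4.99 CPM to 43.0 and 44.8 CPM (3.28, SE 0.45). The chemokine gene Cxcl12 fell from 428 ± 88.6 to 144 ± 23.9 CPM (−1.56, SE 0.20), the kallikrein gene Klk10 from 202 ± 9.89 to 100.3 ± 5.78 CPM (−1.0, SE 0.14) and the interferon-induced GTPase gene Iigp1 from 377 ± 26.5 to 196 ± 12.2 CPM (−0.94, SE 0.14; reads shared with near-identical family members are uncertain). The edgeR adjusted p was 0.0303 for each but Iigp1 (0.0453). All 5 lost the call without db/+ replicate 1 or db/db replicate 2, with values of 1.98 and 2.18 for Hpgd, −1.33 and −1.41 for Cxcl12, −0.95 each for Klk10, −0.86 and −0.88 for Iigp1, and 3.12 and 3.25 for Cyp26b1. Cyp26b1 (3.31), Klk10 (−1.06) and Iigp1 (−1.01) lost it without db/db replicate 1 as well. Hpgd stood at 3.52 without db/+ replicate 2. The count was 0 without db/+ replicate 1, 26 without db/+ replicate 2, 0 without db/db replicate 2, 39 without DAPA replicate 1 and 40 without DAPA replicate 2.

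DAPA called no endothelial-like gene against untreated db/db in edgeR (275 at an unadjusted p under 0.05, where 473.5 are expected by chance) or in DESeq2. Of 7 lists past the threshold, 1 kept the call without any 1 library: genes of endothelial function rose by a median of 0.10, with none of 29 called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.636 with an estimated correlation). The count of genes was 1 without db/+ replicate 2, 2 without DAPA replicate 1 and 4 without DAPA replicate 2.

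Against db/+, treated endothelial-like cells had higher Hpgd (log2 2.56, SE 0.35), the sulfotransferase gene Sult1a1 (2.19, SE 0.27) and Dbp (1.94, SE 0.36), and lower Cxcl12 (−1.29, SE 0.20) and interferon-induced GTPases Gbp7 (−1.30, SE 0.20) and Igtp (−1.24, SE 0.23), with edgeR adjusted p values of 0.0129 to 0.0489. The lists that kept the call without any 1 library were antigen presentation (median −0.73; 2 of 18 lower, 15 adjusted over the list alone; camera adjusted p = 8.83e-13, adjusted p = 0.346 with an estimated correlation). They were also the interferon response (−0.52; 3 of 27 lower, 1 higher and 10 lower adjusted over the list alone, camera adjusted p = 1.55e-06, adjusted p = 0.430 with an estimated correlation) and glucocorticoid-induced genes (0.76; 2 of 20 higher, 11 adjusted over the list alone, camera adjusted p = 3.02e-11, adjusted p = 0.133 with an estimated correlation). Lipid-associated genes (0.56; 2 of 14 higher, 7 adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.594 with an estimated correlation) and adipose genes (1.35; 1 of 6 higher, 3 adjusted over the list alone, camera adjusted p = 0.00609, adjusted p = 0.430 with an estimated correlation) were among them too. The adipose call was lost in looser cells (0.92). EdgeR called 30 genes, 19 higher and 11 lower. Only 3 were called without db/+ replicate 1, and 66 without DAPA replicate 1. Hpgd stood at 3.51 without db/+ replicate 2. Without db/+ replicate 1, Sult1a1 (2.09), Dbp (1.34), Gbp7 (−1.43), Cxcl12 (−1.06) and Igtp (−1.18) lost their calls. Igtp lost it also without db/+ replicate 2 (−1.30) or DAPA replicate 1 (−0.94), Cxcl12 without DAPA replicate 1 (−1.06), and Dbp stood at 2.91 without db/+ replicate 2. Gbp7 and Igtp belong to families of near-identical genes and are uncertain as single genes. Simulated unchanged groups that share their controls gave 0.5 shared calls on average (at most 2) from 3.2 calls in this class, with r across genes at 0.54 against 0.66 measured. Of the 5 genes changed in db/db, 3 were called again in the same direction. That number was 0 without db/+ replicate 1 or db/db replicate 2, 16 without db/+ replicate 2, 6 without db/db replicate 1, 15 without DAPA replicate 1 and 20 without DAPA replicate 2. None moved back, against 1 without DAPA replicate 1 and 3 without DAPA replicate 2.

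Macrophage-like cells of db/db aortas had more transcripts of 7 lipid-associated genes than those of db/+ aortas, and fewer of Retnla and 2 C-type lectin genes. The lipid-associated list rose by a median log2 fold of 1.19, with 7 of 19 members called and 14 adjusted over the list alone (camera adjusted p = 5.95e-08, adjusted p = 0.414 with an estimated correlation). AA467197 (chromosome 2, 122636986 to 122641191) rose from 3.20 ± 3.16 to 109 ± 9.55 CPM (log2 5.01, SE 0.41, edgeR adjusted p = 8.38e-05), the macrophage elastase gene Mmp12 from 22.7 ± 8.87 to 263 ± 296 CPM (3.55, SE 0.78, adjusted p = 0.0466), and the survival gene Bcl2a1a by 3.13 (SE 0.28, adjusted p = 0.000163). Retnla, a marker of alternative activation (chromosome 16, 48842551 to 48844461), fell from 3476 ± 791 to 725 ± 13 CPM (−2.26, SE 0.17, adjusted p = 5.37e-05), and the C-type lectin genes Cd209f and Cd209g by −2.68 (SE 0.40) and −2.67 (SE 0.34, adjusted p = 0.00573 and 0.00261). Bcl2a1a and the Cd209 genes share reads with near-identical family members and are uncertain as single genes. The interferon list fell by −0.66 (2 of 25, 8 adjusted over the list alone; camera adjusted p = 2.47e-07, adjusted p = 0.414 with an estimated correlation) and mitochondrially encoded genes by −0.55 (3 of 13, 9 adjusted over the list alone, camera adjusted p = 1.36e-06, adjusted p = 0.451 with an estimated correlation), as did the median mitochondrial share (3.49% and 4.09% in db/+, 2.87% and 2.57% in db/db). Oxidative stress defence (0.37; 3 of 27, 9 adjusted over the list alone), glucocorticoid-induced genes (0.52; 3 of 16, 6) and clock genes (0.60; 2 of 13, 4) rose, with camera adjusted p values of 3.64e-05, 0.000193 and 0.00159 (adjusted p = 0.405 to 0.414 with an estimated correlation). The cystine transporter gene Slc7a11 rose by 2.46 among them.

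Of 17 lists past the threshold in macrophage-like cells, 8 kept the call without any 1 library. The remaining 2 of these 8 were contractile genes (median −0.70; camera adjusted p = 0.000828, adjusted p = 0.452 with an estimated correlation), abundant in other cells, whose call ended without genes that free RNA could give (−0.06), with doublets kept (−0.12) and in stricter cells (−0.29), and vasoconstriction and vasodilation genes (−0.44, not called with doublets kept, −0.30, or in thinned counts, −0.32, camera adjusted p = 0.00426, adjusted p = 0.451 with an estimated correlation). Resident macrophage genes fell by −0.17 (none of 15 called, 6 lower adjusted over the list alone; camera adjusted p = 0.00469, adjusted p = 0.451 with an estimated correlation), a call lost without db/+ replicate 1 (−0.06). EdgeR called 116 of 8331 genes, 83 higher and 33 lower, against 32 without db/+ replicate 1, 63 without db/+ replicate 2, 63 without db/db replicate 1 and 45 without db/db replicate 2. AA467197 stood at 4.30 without db/+ replicate 1 and 6.64 without db/+ replicate 2. Mmp12 lost its call without db/+ replicate 1 (3.20), db/+ replicate 2 (4.01) or db/db replicate 1 (1.22), and stood at 4.36 without db/db replicate 2. Cd209f lost its call without db/db replicate 2 (−2.26), and without db/db replicate 1 Cd209f stood at −3.40 and Cd209g at −3.76.

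**Figure D4:**
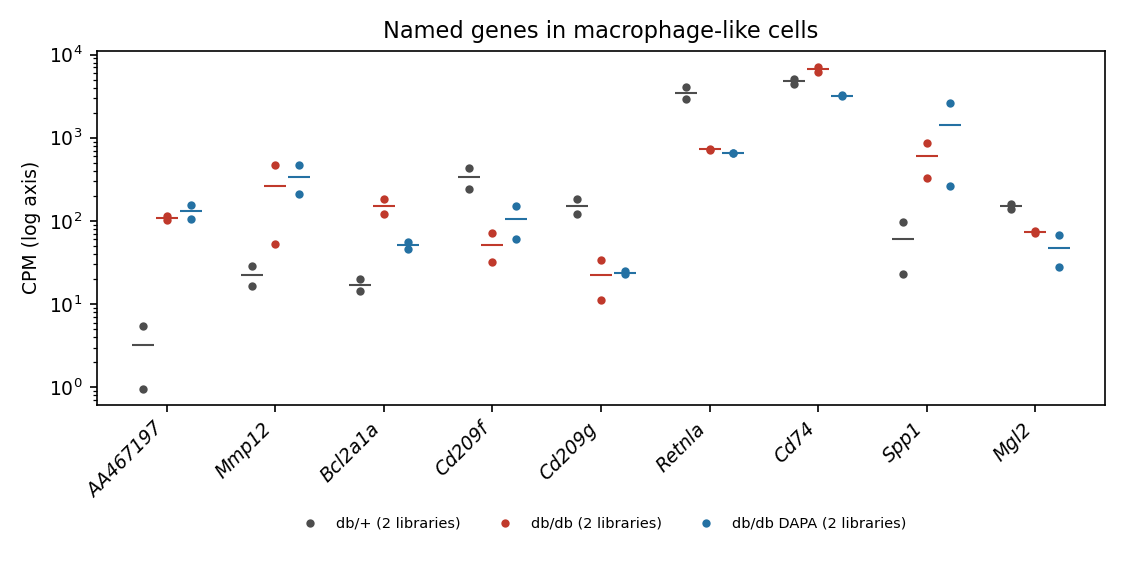
Levels of the genes named by rule in macrophage-like cells, in CPM on a log axis; each point is 1 library and each bar the mean of the 2 libraries of a group. Retnla stands at 3476 CPM in db/+, 725 CPM in db/db and 653 CPM in DAPA, while the points of Spp1 and Mmp12 lie far apart within a group.

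Under DAPA, macrophage-like cells had less of the antigen-presentation chaperone gene Cd74 (chromosome 18, 60803848 to 60812652) than in untreated db/db aortas. Cd74 fell from 6634 ± 678 to 3197 ± 57.1 CPM (log2 −1.05, SE 0.13, edgeR adjusted p = 0.0263) and was the only call; it stood at 4777 ± 472 CPM in db/+. The oxidative phosphorylation list rose by a median of 0.23 with none of 56 members called by either adjustment (camera adjusted p = 1.05e-06, adjusted p = 0.627 with an estimated correlation), the 1 of 11 lists past the threshold that kept the call without any 1 library. Antigen presentation fell by −0.44 (1 of 18, 5 adjusted over the list alone; camera adjusted p = 0.00135, adjusted p = 0.627 with an estimated correlation), a call lost without DAPA replicate 1 (−0.08). Lipid-associated genes rose by a further 0.38 (none of 19 over all genes, 3 adjusted over the list alone; camera adjusted p = 0.00242, adjusted p = 0.627 with an estimated correlation), lost without db/db replicate 2 (0.10) or DAPA replicate 2 (0.10). There were 491 genes at an unadjusted p under 0.05, where 417 are expected by chance, and DESeq2 called 3. Cd74 lost its call without db/db replicate 2 (−0.95), DAPA replicate 1 (−1.08) or DAPA replicate 2 (−1.03), and with doublets kept (−0.97). The count was 2 without db/+ replicate 1 or db/+ replicate 2, 7 without db/db replicate 1 and 3 without DAPA replicate 1.

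Against db/+, lipid-associated genes of treated macrophage-like cells rose by a median of 1.56, 10 of 19 members over all genes and 15 adjusted over the list alone (camera adjusted p = 8.55e-12, adjusted p = 0.378 with an estimated correlation). The lipid receptor gene Trem2 rose by 1.56 (SE 0.20; 168 to 500.3 CPM), the fatty acid binding protein gene Fabp4 by 2.14 and Lpl by 3.17 (4.03 without db/+ replicate 2). Osteopontin (Spp1) rose by 4.52 (SE 0.89, edgeR adjusted p = 0.0252), AA467197 by 5.33 (SE 0.40, adjusted p = 3.33e-05) and Mmp12 by 3.84 (SE 0.79, adjusted p = 0.0310). Cd209g (−2.63), Retnla (−2.41) and Mgl2, a galactose-binding lectin (−1.89), fell, with adjusted p values of 2.85e-05 to 0.00744. Timd4, a receptor of resident macrophages, fell by −1.52 (−2.12 without DAPA replicate 1). Lists that kept the call without any 1 library were also collagens (−1.02; −2.48 without DAPA replicate 1), elastic fibre and other matrix (−0.85; −1.98 without DAPA replicate 1), both abundant in other cells and not testable without genes that free RNA could give, and contractile genes (−1.13; −2.30 without DAPA replicate 1, and −0.12 and not called without genes that free RNA could give). So were vasoconstriction and vasodilation genes (−0.56, and not called without genes that free RNA could give, −0.12, or in thinned counts, −0.41), glycolysis (0.36), oxidative phosphorylation (0.20) and oxidative stress defence (0.22), with camera adjusted p values of 8.16e-08 to 0.00266 (adjusted p = 0.378 to 0.417 with an estimated correlation). EdgeR called 124 genes, 85 higher and 39 lower (29 without db/+ replicate 1, 81 without DAPA replicate 2). Again 60 of the 116 genes changed in db/db (51.7%) were called in the same direction (12 without db/+ replicate 1, 38 without db/db replicate 1 and 35 without db/db replicate 2). None moved back, against 5 without db/db replicate 1 and 1 without db/db replicate 2. Both comparisons with db/+ share its libraries, and Pearson's r across genes between their log2 folds was 0.73, against 0.49 in simulated unchanged groups. AA467197 stood at 4.61 without db/+ replicate 1 and 6.96 without db/+ replicate 2. Spp1 lost its call without db/+ replicate 1 (3.83) or DAPA replicate 2 (2.11) and stood at 5.90 without db/+ replicate 2 and 5.39 without DAPA replicate 1. It was not called in stricter cells (1.58), with doublets kept (4.72), with DESeq2 (4.56) or in a fit of 2 groups only (4.51). Mmp12 lost its call without db/+ replicate 1 (3.49), db/+ replicate 2 (4.30) or DAPA replicate 2 (3.22), and Mgl2 without DAPA replicate 1 (−1.19).

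Some genes moved in several classes. In db/db against db/+, mt-Nd4, mt-Nd4l, mt-Nd5 and Zbtb16 were called in at least 3 of the 4 classes, and in DAPA against db/+, Cxcl12 and Dbp were called in all 4. Of the smooth muscle-like calls of db/db against db/+ that were also tested in fibroblast-like cells, 75.8% of 801 had the same direction there, against 61.1% of all genes; 45 were called in both in the same direction and 1 in the opposite one. The share was 73.9% of 641 in endothelial-like and 66.4% of 464 in macrophage-like cells, against 60.5% and 56.1% of all genes. Free RNA from smooth muscle-like cells could give the same direction in other classes, and was not set apart here. The class by group interaction in edgeR, which takes out what moves both classes alike, found 223 of 14827 genes whose change differed between smooth muscle-like and fibroblast-like cells, 98 higher and 125 lower in smooth muscle-like cells. It found 129 of 14838 between smooth muscle-like and endothelial-like cells, 77 higher and 52 lower. Among the smooth muscle-like calls, 107 of 1029 and 68 of 1026 were such genes. The 223 were 340 without db/+ replicate 1 and 87 without db/+ replicate 2, and the 129 were 85 without db/+ replicate 1.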

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

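Tests chosen only after the results were seen are those of batches acting alike on every class, of genotype or batch by class, of digestion, of glucocorticoids beyond the clock, and of free RNA in parts of the lipid-associated list; those of mitochondrial share, clock phase and free RNA in the whole list were set first.

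The change of some genes differed between smooth muscle-like cells and another class, in both directions, and these tested differences singled the results out. In db/db against db/+, the change in smooth muscle-like minus that in fibroblast-like cells was 1.85 for Sparcl1 (SE 0.18, edgeR adjusted p = 1.78e-05), 1.83 for Aspn (SE 0.18, adjusted p = 1.78e-05), 1.07 for Dbp (SE 0.16, adjusted p = 0.000861), and 0.97 for Mt2 (SE 0.12, adjusted p = 0.000171). Against endothelial-like cells it was 2.12 for Aspn (SE 0.41), 1.63 for Sparcl1 (SE 0.16), 1.27 for Mt2 (SE 0.20) and 1.16 for Dbp (SE 0.23), with adjusted p values of 3.31e-11 to 0.000967. In DAPA against db/+, smooth muscle-like minus fibroblast-like cells gave 1.57 for Mt2, 1.27 for Dbp, 1.09 for Mt1, −0.61 for Cacybp and −0.93 for Tent5a (adjusted p values of 8.01e-07 to 0.0278). Smooth muscle-like minus endothelial-like cells gave 1.23 for Dbp, 1.15 for Mt2, 1.11 for Tef, −1.08 for Lmcd1 and −1.59 for Gdf15 (7.08e-08 to 0.000407).

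Between smooth muscle-like and fibroblast-like cells, 223 genes differed in the change of db/db against db/+ (340 without db/+ replicate 1, 87 without db/+ replicate 2). There were 2 in DAPA against db/db (25 without either db/+ library, 6 without db/db replicate 1, 17 without db/db replicate 2, 0 without DAPA replicate 1) and 181 in DAPA against db/+ (113 without db/+ replicate 2, 292 without db/db replicate 1, 66 without DAPA replicate 1). Between smooth muscle-like and endothelial-like cells the numbers were 129 (85 without db/+ replicate 1), 12 and 143. The 12 were 27 without either db/+ library, 21 and 38 without db/db replicates 1 and 2, and 74 and 23 without DAPA replicates 1 and 2.

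The first pattern weighed is the set of smooth muscle-like genes changed between db/db and db/+. Lower RNA quality in db/+ cells, seen in their mitochondrial share, would shrink the folds in stricter cells. Their median ratio to the folds in all kept cells was 0.934 (0.920 to 0.953 over resampled genes), with 1007 of 1020 genes keeping their sign. However, only 530 genes were called there and the modulated and inflammatory lists turned. Genes are not independent, so the interval does not cover differences between libraries. Stricter cells are also a part of the same cells, with 2155 of 5957 smooth muscle-like cells left in db/+ replicate 1 and 597 of 6120 in db/+ replicate 2. A batch difference acting alike on every class would give fibroblast-like cells the same folds, which the interaction test over all genes argues against for 107 of 1029 smooth muscle-like calls; for the remaining 922 it cannot be told apart, since their folds were not found to differ. Genotype, or a batch difference that acts by class, cannot be told apart, because 0 db/+ libraries are in batch 1.

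The second pattern is the rise of clock and glucocorticoid-induced genes in both db/db groups. Digestion raises immediate early genes, and that list moved down in macrophage-like cells of DAPA against db/+ (median −0.31 without clock and glucocorticoid genes; unadjusted camera p = 0.00054, and 0.0758 with an estimated correlation) while in smooth muscle-like cells it stood at 0.18 (unadjusted camera p = 0.0350, and 0.556 with an estimated correlation). The call of the whole list there ended in the 1 cluster shared by all libraries (−0.13), with the replicate block (0.19), in stricter cells (0.14), and without db/+ replicate 1 (0.16) or DAPA replicate 1 (0.19). Digestion stays open. A shift of clock phase between the collections may explain the clock genes: Arntl, which peaks opposite to Dbp, stood at −1.19 in smooth muscle-like cells (edgeR adjusted p = 0.0581) and −1.90 in DAPA against db/+ (adjusted p = 0.01). Glucocorticoid exposure beyond the clock stays open as well. The glucocorticoid list without clock and immediate early genes rose with both correlations in 5 of 8 comparisons at an unadjusted camera p under 0.05. Neither comparison in smooth muscle-like cells was among them (unadjusted camera p = 0.0613 and 0.0574 with an estimated correlation). These genes are part of the pattern itself and the comparisons share libraries, so this rise cannot decide the explanation. Collection times are not given in the sources used here, and these explanations cannot be told apart.

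The third pattern is the rise of lipid-associated genes in macrophage-like cells of both db/db groups. Free RNA from other cells stays possible for the whole list, since only 5 of its 10 called members were highest in macrophage-like cells, the bound set in advance. The list was then split, after that result was seen. For Itgax, Mmp12, Lgals3, Trem2 and Spp1 the level in macrophage-like cells was at least 10.4 times that in any other tested class in each db/db library (lowest for Lgals3), which argues against free RNA. For the others, what free RNA could bring was estimated from the median share of each class's RNA that its markers allow in macrophage-like cells. A class whose markers mostly had no count got a share of 0, as endothelial-like cells did in DAPA replicate 2. The estimate is therefore not an upper limit. Fabp5, Ctsd and Lpl rose over db/+ by at least 22.0 times that amount in each library of both db/db groups. Because the amount is not an upper limit, free RNA is not excluded for them. For Fabp4 and Cd9 the smallest ratio was 1.09, and free RNA cannot be told apart from a rise. A looser share, from all abundant genes highest in a class, was run first and set 0 of these 5 apart. A batch difference acting alike on every class would move the list elsewhere too. Over the members tested in both classes, called or not, a class's median was divided by that in macrophage-like cells. In smooth muscle-like and fibroblast-like cells the largest ratio was 0.324 (−0.00841 to 0.722 over resampled members, and at most 0.746 in the other comparisons), under the 0.8 set for it. Endothelial-like cells, where the list also rose in DAPA against db/+, were left out of this test, so it does not speak for them. Nor does it speak for members that a class barely holds, such as Itgax (0 CPM in fibroblast-like cells), which could not enter it. The list was singled out for its rise in macrophage-like cells, which favours a low ratio. The test therefore does not settle this explanation. Genotype, or a batch difference acting on macrophages, stays open with 0 db/+ libraries in batch 1.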

How the results depend on the processing

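The fits without mitochondrial genes and in 1 cluster shared by all libraries were chosen after seeing the data; the other alternatives were planned. Of 238 calls of named genes and list members, 237 held with RLE size factors, 212 in DESeq2, 183 in stricter cells and 134 without db/+ replicate 1. Of 137 list calls, 136, 135, 107 and 109 held. Over all alternatives 9242 of 10437 values for genes and 5727 of 6256 for lists kept their direction and side of the threshold, and 374 of 378 for shares.

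In smooth muscle-like cells the 1049 genes of db/db against db/+ and the 1157 of DAPA against db/+ became 1699 and 1847 with no filter on low counts, 530 and 590 in stricter cells, and 590 and 686 in the shared cluster; leaving out 1 library gave 448 to 855 and 353 to 1347. Of the 530 and 590 of db/db against db/+, 443 and 436 were among the 1049. DAPA against db/db had 0, against 92 (no filter), 31 (DESeq2), 4 (replicate block, that is the replicate number as block) and 0 to 3 without 1 library. Genes kept changed went from 691 to 1158 (no filter), 356 (stricter cells), 365 (shared cluster) and 303 to 538 without 1 library, and genes moved back from 0 to 28 (no filter), 7 (DESeq2), 1 (block) and 0 to 2.

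In fibroblast-like cells the 108, 1 and 93 genes became 593, 88 and 518 with no filter, 259, 6 and 229 with the block, and 65, 0 and 55 in stricter cells, with 12 to 112, 0 to 3 and 12 to 87 without 1 library. The 1 was also 3 in DESeq2 and 0 at resolution 2 and in thinned counts, and the 93 became 145 with doublets kept. Kept genes (56) were 326 with no filter, 34 with 2 groups only, 146 with the block, 31 in stricter cells and 8 to 56 without 1 library; genes moved back (0) were 38 with no filter, 1 in DESeq2, 2 with the block and 0 to 0 without 1 library.

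In endothelial-like cells the 5 genes of db/db against db/+ became 172 with no filter, 16 in DESeq2, 35 with 2 groups only, 21 with the block, 14 with doublets kept, 12 in stricter cells, 3 in looser cells, 25 at resolution 2, 3 in thinned counts, 23 without free RNA genes and 0 to 40 without 1 library; 62.5% were higher in DESeq2 against 40.0%. The 0 of DAPA against db/db became 41 (no filter), 1 (block) and 0 to 4, and the 30 of DAPA against db/+ became 242 (no filter), 58 (block), 6 (looser cells), 59 (resolution 2), 11 (thinned), 59 (without free RNA genes) and 3 to 66. Kept genes (3) were 106 (no filter), 12 (DESeq2), 14 (2 groups only), 17 (block), 11 (doublets kept), 8 (stricter cells), 18 (resolution 2), 18 (without free RNA genes) and 0 to 20; genes moved back (0) were 14 with no filter and 0 to 3.

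In macrophage-like cells the 116 became 339 (no filter), 70 (DESeq2), 36 (doublets kept), 71 (thinned) and 32 to 155 without 1 library. The 1 became 72 (no filter), 3 (DESeq2), 2 (2 groups only), 4 (block), 0 (doublets kept), 4 (stricter cells), 6 (resolution 2), 2 (thinned), 3 (without free RNA genes) and 1 to 7, and the 124 became 419 (no filter), 48 (doublets kept) and 29 to 124. Kept genes (60) were 199 (no filter), 25 (doublets kept) and 12 to 57; genes moved back (0) were 25 (no filter), 2 (block), 1 (stricter cells), 1 (without free RNA genes) and 0 to 5.

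Genes differing between smooth muscle-like and fibroblast-like cells (223, 2 and 181) became 412, 67 and 381 with no filter, 126, 0 and 79 in stricter cells, and 87 to 340, 0 to 25 and 66 to 292 without 1 library; DESeq2 gave 141 and 4 for the first 2, and the 2 was 1 with doublets kept, 6 at resolution 2 and 8 in thinned counts. Against endothelial-like cells (129, 12 and 143) DESeq2 gave 54, 1 and 53, stricter cells 75, 6 and 66, leaving out free RNA genes 62, 1 and 78, and leaving out 1 library 85 to 187, 21 to 74 and 135 to 164; the 129 was 73 in thinned counts and the 12 was 25 with no filter. Class shares changed in 0 classes, 2 in stricter cells for DAPA against db/+, and 0 to 1, 0 to 0 and 0 to 1 without 1 library.

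The direction of camera's test turned for these lists, given as medians. In stricter cells they were, for smooth muscle-like cells, modulated smooth muscle (−0.21 in db/db and −0.089 in DAPA, against db/+), inflammatory genes (−0.22 and −0.10) and oxidative phosphorylation (0.0136 in DAPA against db/+), with the genes Cd34 (−0.11), Lgals3 (−0.11) and Thbd (−0.0221) in DAPA against db/+. Resident macrophage genes in smooth muscle-like cells turned without DAPA replicate 1 in DAPA against db/db (−0.53 to 0.27 over left-out libraries) and without DAPA replicate 2 in DAPA against db/+ (−0.25 to 0.14). In fibroblast-like cells proliferation turned with no filter (−0.83) and without db/+ replicate 1 (−0.80 to 0.20 over left-out libraries) in db/db against db/+, and contractile genes with doublets kept (−0.22) and at resolution 2 (−0.13) in DAPA against db/db. In endothelial-like cells contractile genes turned in looser cells (−0.32, db/db against db/+) and inflammatory genes without DAPA replicate 1 (−0.0896 to 0.46 over left-out libraries, DAPA against db/db). In macrophage-like cells proliferation turned without db/+ replicate 1 (−0.16 to 0.56 over left-out libraries, db/db against db/+) and matrix proteases without free RNA genes (0.56, DAPA against db/+). The cause was not tested for any of these changes.

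Depth, pools and batch set the limits. A left-out library leaves its group with 1. In 1 simulation of db/db against db/+, 67 genes were changed 1.5-fold, 67 2-fold and 66 4-fold in each class. There 186 calls were made in smooth muscle-like, 124 in fibroblast-like, 105 in endothelial-like and 93 in macrophage-like cells. The number of changed genes was set alike for every class, so these counts cannot be compared with the measured ones. Why the measured counts differ between classes was not tested. The replicate numbers are not stated to pair the libraries, and residuals of libraries with the same number correlated by −0.15 to 0.19 over classes and pairs of groups.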

Other observations

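All tests named in this part belong to those listed above; no further hypothesis was tested.

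Transcription factors of the clock did not all move alike in smooth muscle-like cells. Npas2, a partner of the core activator, was lower by −1.44 in db/db against db/+ (SE 0.37, edgeR adjusted p = 0.0451) and by −1.76 in DAPA against db/+ (SE 0.38, adjusted p = 0.0216), while the target Dbp rose in both. In db/db against db/+, Clock fell by −0.33 (adjusted p = 0.0443), Arntl was not called (−1.19, adjusted p = 0.0581), and Cry1 (0.00355, adjusted p = 0.991) and Nfil3 (−0.0144, adjusted p = 0.969) were not called either.

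Lipid-associated genes were uneven between libraries of a group in macrophage-like cells. Mmp12 stood at 472 and 53.4 CPM in the 2 db/db libraries, and Spp1 at 261 and 2596 CPM in the 2 DAPA libraries. Trem2 varied less, at 390 and 308 CPM in db/db and 419 and 581 CPM in DAPA.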
